A study of Mus musculus with 10 samples.

How the data were processed

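RNA from primary mouse aortic smooth muscle cells was measured on 6 Affymetrix Mouse Genome 430 2.0 arrays, 2 for each of 3 groups. Per the labels' protocols, the cells came from the thoracic aortas of C57BL/6 mice aged 8 weeks, had been passaged at most 5 times and grew in medium with 10% fetal bovine serum. One group was harvested at baseline. A second group was loaded for 72 h with cholesterol at 10 µg/mL, carried by methyl-β-cyclodextrin at a molar ratio of 1 to 6. The HDL group was loaded in the same way and then kept for a further 72 h with human high-density lipoprotein (HDL) at 100 µg/mL, so that its harvest came 144 h after loading began. No group loaded with cholesterol and harvested at that later time was analysed here. The labels list no cyclodextrin and no loading time for the baseline group. No group given the carrier alone, or kept for 72 h without cholesterol, was analysed here either.

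Per the labels and the design text, the authors background-adjusted and normalized the probe intensities with Robust Multichip Average (RMA) and summarised them per gene with a custom probe mapping of the University of Michigan, built on Ensembl release 59. The deposited values are log2 RMA values for 16860 genes. The authors normalized the arrays in separate runs: analysis I held the baseline and cholesterol arrays, and analysis II held all 3 groups. The table therefore has 10 columns for 6 arrays, and the second version of the 4 baseline and cholesterol arrays was not counted as further replicates. Versions of the RMA software are not given in the sources used here. RMA brings the arrays to one distribution, so a change in the total amount of RNA per cell would not show, and its background step compresses changes of dim genes. The number of arrays limits the precision.

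Arrays were grouped by their labels. The labels number the arrays 1 and 2 within each group but do not say whether these came from separate cultures, cell isolates or mice, nor do they give the sex of the mice. The p-values therefore measure only the spread between these samples, which may be technical.

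All tests used the deposited log2 values without further normalization or filter. Cholesterol was compared with baseline in analysis I, as in the authors' design, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term). HDL was compared with cholesterol and with baseline in analysis II in one fit of the 3 groups, which share an estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 16860 genes. The authors' design text names a one-way test per gene with the same adjustment; that test leaves 2 residual degrees of freedom for analysis I and was run as an alternative. The residual degrees of freedom of the limma fits were 2 and 3, to which the prior added 4.52 and 4.03.

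Genes called for cholesterol were also related to the HDL comparisons, all in analysis II. The share of the cholesterol change undone after HDL is minus the HDL against cholesterol change divided by the cholesterol against baseline change, so that 0 is no return and 1 is a full return to baseline. Because these comparisons share arrays, 50 sets of 6 arrays were simulated from the fitted gene means and spreads with no difference between groups. A further 50 had HDL equal to cholesterol and 50 had HDL equal to baseline. The noise was drawn independently for each gene, with the same spread in all groups. The tests were not repeated on split controls, since no part of a group of 2 would keep 2 arrays.

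The files do not pair the Ensembl identifiers with gene names. The reference table of the mouse assembly GRCm38.p6 matched 0 of them, so genes are given by identifier only. The naming rule was fixed before the data were examined, as were the groups, the tests and most alternatives. It took the genes with the largest rise and fall among called genes whose groups of arrays did not overlap and that have a symbol. With no symbols it was reduced to the 2 largest rises and 2 largest falls per comparison. The 24 gene lists fixed beforehand by symbol, with 647 entries for macrophage, smooth muscle, sterol and other genes, and a set of marker genes fixed by symbol could not be matched and were not tested. A further 4 genes were looked at by identifier as possibly sex-linked after the results of ENSMUSG00000069045_at were seen; their identity was not checked.

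In place of those lists, 3 lists of cell cycle genes were used, which was decided after the deposited table had been read but before the values of any of these genes were seen. They come from the mouse marker pairs for cell cycle phase supplied by Ensembl identifier with the scran package, an external list. A gene entered the list of a phase when it was the higher member of at least 10 pairs and of at least 90% of its pairs there, and 25 genes that entered more than 1 list were left out. Of 134 G1, 99 S and 95 G2M genes, 125, 95 and 91 were measured. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 3 lists, and again with an estimated correlation. The rotation test fry was run beside it; it asks whether a list moves on balance in one direction, without comparing it with other genes.

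The test was checked on simulated data with the spread of these arrays, in 20 draws with 200 of 16860 genes changed. For cholesterol against baseline, 47.2% of genes changed by 0.6 on the log2 scale were called, 94.6% of those changed by 1 and 99.7% of those changed by 2, and 4.19% of calls were false. For HDL against cholesterol these shares were 33.7%, 86.3% and 99.3%, and 5.47% of calls were false. In these draws the spread of each gene came from its posterior distribution; an earlier simulation that took the fitted spread as the true one gave a higher share of false calls and was replaced, while the limma fit stayed as it was. A list shifted by 0.3 had an unadjusted camera p under 0.05, at the preset correlation, in 20 of 20 draws for both comparisons. The noise in these draws was independent between genes, so they do not show how the list test does with genes that move together. Each gene also had the same spread in all groups, as limma assumes. The real HDL replicates lay further apart (SD of the difference 0.27) than those at baseline (0.17) and after cholesterol (0.18). The shares of false calls therefore do not show how the test does with such unequal groups.

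Alternatives were a filter on the 40% dimmest genes, a trend between mean and variance, robust moderation, a further quantile normalization, median centring, the replicate number as a block, leaving out each array, a minimum change of 1 on the log2 scale, the other deposited normalization, fits of only the groups compared and the one-way test per gene. Array quality weights and a share undone from separate arrays were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.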

Results

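Gene expression was measured in primary mouse aortic smooth muscle cells at baseline, after cholesterol loading for 72 h, and after the same loading followed by 72 h with HDL, with 2 arrays per group. Values are log2 RMA values of 16860 genes, and their median on the arrays lay between 6.93 and 6.98 when the 3 groups were normalized together. Replicate arrays correlated across genes by 0.998 at baseline, 0.997 after cholesterol and 0.994 after HDL. The SD of the difference between replicates was 0.17, 0.18 and 0.27 on the log2 scale in these groups. The number of genes that differed by at least 1 between replicates was 3, 17 and 153. Between groups, cholesterol and HDL arrays correlated by 0.987 to 0.994, while baseline arrays correlated with cholesterol arrays by 0.969 to 0.974 and with HDL arrays by 0.967 to 0.975. Across genes, which are not independent replicates, the first principal component took 71.4% of the variance and set the baseline arrays apart from the other 4. The second took 17.9% and set the cholesterol arrays apart from the HDL arrays.

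Cholesterol-loaded cells were compared with baseline cells to ask which genes change with loading, in a study concerned with macrophage features that smooth muscle cells acquire. The largest rise was that of ENSMUSG00000026822_at, from a mean log2 value of 4.72 ± 0.28 (SD, n = 2) at baseline to 14.44 ± 0.10 (SD, n = 2), a change of 9.71 ± 0.14 (SE; adjusted p = 8.63e-07). Its level thus went from the 20.1st to the 99.9th percentile of the genes on an array. ENSMUSG00000029371_at rose by 9.07 ± 0.09 (SE; adjusted p = 1.48e-07), from 4.03 ± 0.07 to 13.10 ± 0.02 (SD, n = 2 each). The largest fall was that of ENSMUSG00000021390_at, which changed by -5.69 ± 0.10 (SE; adjusted p = 1.26e-06), from 11.88 ± 0.14 to 6.18 ± 0.06 (SD, n = 2 each). ENSMUSG00000069045_at changed by -5.07 ± 0.12 (SE; adjusted p = 3.45e-06), from 8.99 ± 0.05 to 3.92 ± 0.22 (SD, n = 2 each), and after loading lay at the 6.26th percentile of the arrays. The labels do not say whether baseline and loaded cells were of the same isolate or from mice of the same sex. In every comparison with baseline, that of ENSMUSG00000069045_at included, the origin of the cells and the loading thus cannot be told apart. Without a group given the carrier alone or kept for 72 h without cholesterol, the carrier and the time in culture cannot be told apart from cholesterol either.

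In all, limma called 4919 of 16860 genes (29.2%), of which 2214 rose and 2705 fell, and 6625 genes had an unadjusted p under 0.05. Among the called genes 508 rose and 454 fell by at least 1 on the log2 scale. Changes of at least 3 were more often rises, with 64 genes against 13 that fell. The median size of a called change was 0.57, with the smallest at 0.27. The second deposited normalization, fitted with all 3 groups, called 3960 genes. Of these, 3871 were also called in the first, all in the same direction. Fitted with the 4 baseline and cholesterol arrays alone, the second normalization called 4915 genes, 4645 of them also called in the first. The lower count of 3960 thus goes with the 3-group fit, while the normalization itself left the count of 4919 nearly unchanged. The count was 2671 without baseline replicate 1 and 2744 without baseline replicate 2. The one-way test per gene called 38 genes, 37 of them among the limma calls, with 4844 at an unadjusted p under 0.05; it left ENSMUSG00000026822_at, ENSMUSG00000021390_at and ENSMUSG00000069045_at at adjusted p values of 0.0604, 0.0600 and 0.0651.

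Genes that mark the G2 and M phases of the cell cycle, when cells prepare for and pass through division, fell with cholesterol loading. Of 91 measured members of the G2M list 59 fell, 7 rose and 25 were not called, and 38 fell by at least 1 on the log2 scale. The counts adjusted over the list alone were 62 and 8. The mean change of the list was -0.90 and its median -0.64 (camera adjusted p = 5.49e-14; adjusted p = 0.102 with an estimated correlation; fry adjusted p = 0.00596). The list mean lay at 8.17 and 8.26 on the baseline arrays and at 7.28 and 7.35 on the cholesterol arrays. Of the S phase list, whose genes mark DNA replication, 33 of 95 members fell and 11 rose, and 38 and 14 with p adjusted over the list alone. Its mean change was -0.26 (camera adjusted p = 0.0112; adjusted p = 0.225 with an estimated correlation). That S list call was also lost when dim genes were left out (adjusted p = 0.0509) and without baseline replicate 2 (adjusted p = 0.0797). Of the G1 list 37 of 125 members fell and 20 rose (41 and 20 over the list alone), with a mean change of -0.16 that did not pass the list test (camera adjusted p = 0.161; adjusted p = 0.634 with an estimated correlation). With the preset correlation it passed without baseline replicate 1 (adjusted p = 0.0441) and without cholesterol replicate 1 (adjusted p = 0.0386).

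**Figure D1:**
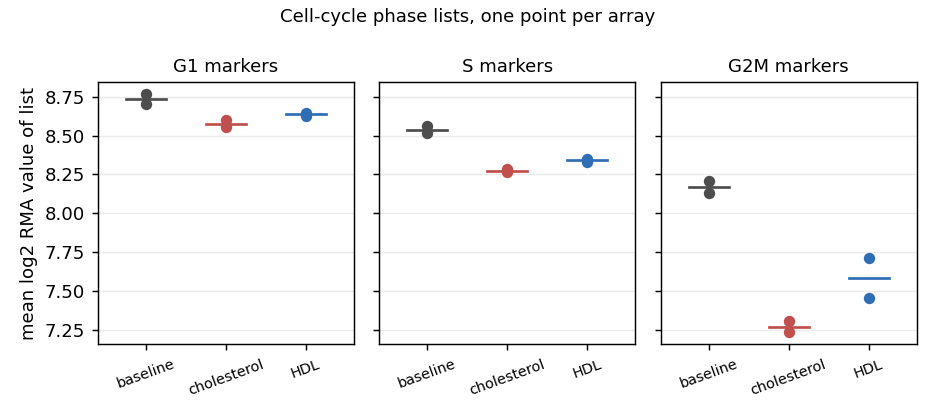
Mean log2 RMA value of the measured genes of the G1, S and G2M lists (vertical axis) in baseline, cholesterol and HDL cells, all from the second deposited normalization. Each point is 1 array and each bar the mean of 2 arrays; the G2M mean was 8.13 and 8.21 at baseline, 7.23 and 7.31 after cholesterol, and 7.71 and 7.46 after HDL, while the axis does not start at 0.

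Loaded cells treated with HDL were compared with loaded cells harvested before that treatment, to ask what changes when HDL, an acceptor of cellular cholesterol, is added. ENSMUSG00000020641_at rose from 6.04 ± 0.18 to 10.18 ± 0.78 (SD, n = 2 each), a change of 4.14 ± 0.33 (SE; adjusted p = 0.00187). ENSMUSG00000028037_at rose from 7.66 ± 0.30 to 11.25 ± 0.37 (SD, n = 2 each), a change of 3.59 ± 0.28 (SE; adjusted p = 0.00155). With cholesterol alone these genes had changed by 0.43 ± 0.33 (SE; adjusted p = 0.431) and 1.17 ± 0.28 (SE; adjusted p = 0.0221). The falls went against earlier rises: ENSMUSG00000035042_at, which had risen by 5.90 with cholesterol, changed by -2.84 ± 0.40 (SE; adjusted p = 0.0178), and ENSMUSG00000028238_at, which had risen by 2.90, changed by -2.21 ± 0.10 (SE; adjusted p = 0.000308). The call of ENSMUSG00000035042_at was lost without cholesterol replicate 1 (adjusted p = 0.0634) and without either baseline array (adjusted p = 0.0758). None of these genes passed the one-way test per gene.

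**Figure D2:**
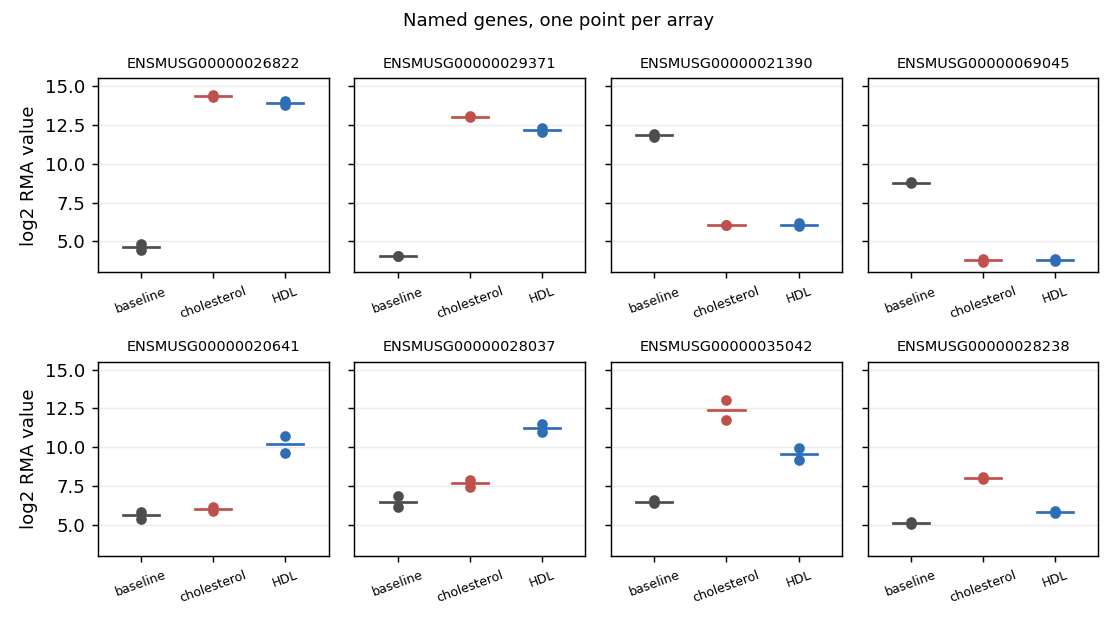
Log2 RMA values (vertical axis, second deposited normalization) of the 8 genes named by identifier in baseline, cholesterol and HDL cells. Each point is 1 array and each bar the mean of 2 arrays; in the upper row the HDL arrays lie near the cholesterol arrays, and in the lower row ENSMUSG00000028238_at went from 5.13 at baseline to 8.03 after cholesterol and 5.82 after HDL.

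HDL treatment changed 461 genes against cholesterol (2.73%), with 301 that rose and 160 that fell, and 3034 genes had an unadjusted p under 0.05 in limma. By at least 1 on the log2 scale 127 rose and 43 fell. Single arrays moved this count: it was 74 without cholesterol replicate 1, 138 without cholesterol replicate 2, 145 without either baseline array, and 1656 without HDL replicate 2. The one-way test per gene called 0 genes, with 1577 at an unadjusted p under 0.05 and a smallest adjusted p of 0.280, and limma on the cholesterol and HDL arrays alone called 145. Leaving out either baseline array amounts to that same fit, because a lone baseline array adds nothing to the estimate of the spread. The HDL cells were harvested 72 h later than the cholesterol cells, and the time in culture and the treatment cannot be told apart.

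The comparisons were then joined to ask how far the cholesterol response was undone after HDL. Of the 3960 genes called for cholesterol in the second normalization, 242 (6.11%) were called in the opposite direction after HDL. These were 109 genes that had risen and 133 that had fallen, where independent lists would share 16.7 and 39.3. Relative to baseline, 109 of the 242 were still called in the direction of the cholesterol change, 123 were not called and 10 were called in the other direction. In sets simulated with HDL equal to cholesterol the mean count was 0.02. No gene truly differed between HDL and cholesterol in those sets, so almost none could be called and the low count is fixed by that setting. It does not show how many of the 242 come from the shared cholesterol arrays. Sets with no difference between groups gave 0.02 as well, but had a mean of only 0.12 genes called for cholesterol. Across genes the cholesterol change and the HDL against cholesterol change correlated by -0.278, against -0.129 simulated with HDL equal to cholesterol and -0.498 with no difference between groups. The covariance was -0.0469 against -0.0115 in both kinds of simulated sets, a difference of -0.0355. The count was 20 without cholesterol replicate 1, 60 without cholesterol replicate 2, 45 without either baseline array and 667 without HDL replicate 2. Part of any excess may come from the cholesterol arrays that both comparisons share.

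The larger part of the cholesterol calls was also called against baseline after HDL. Of the 3960 genes 2510 (63.4%) were called against baseline in the same direction after HDL, 1095 of them higher and 1415 lower than at baseline, where independent lists, which leave out the shared baseline arrays, would share 161 and 239. Sets simulated with HDL equal to cholesterol had a mean of 3892 such genes of 4684 called for cholesterol. The sets with no effect gave a mean of 0.02, which is fixed by their few calls. The median share of the cholesterol change undone was 0.231, with quartiles of -0.0199 and 0.466. It was 0.228 for genes that had risen, 0.232 for genes that had fallen and 0.170 for the 949 genes changed by at least 1. Simulated sets gave 0.0355 with HDL equal to cholesterol and 0.965 with HDL equal to baseline. These sets took the observed means, with their noise, as the true ones, and so called more genes than the data (4684 against 3960). The value of 0.0355 may therefore understate how far choosing genes on the cholesterol arrays raises the share. The HDL arrays taken singly gave 0.195 and 0.258. When genes changed by at least 1 were chosen on arrays of one replicate number (1052 and 937 genes) and the share taken from the other, the median was 0.143 and 0.171 and the ratio of summed changes was 0.111 and 0.154. The count of 2510 was 1104 and 973 without baseline replicate 1 or 2, and 1503 and 1649 without cholesterol replicate 1 or 2.

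**Figure D3:**
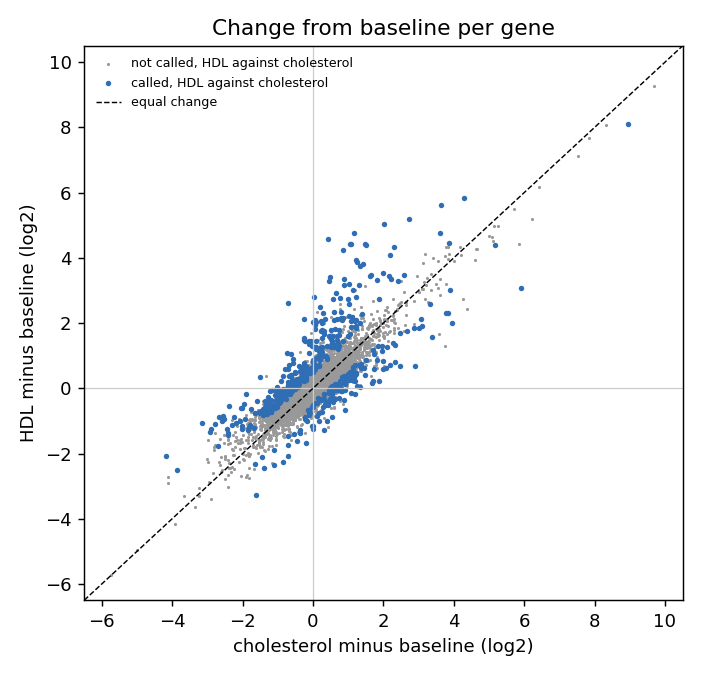
Log2 change from baseline of each of 16860 genes after cholesterol (horizontal axis) and after cholesterol followed by HDL (vertical axis), second deposited normalization. Larger blue points are the 461 genes called for HDL against cholesterol, grey points the others, and the dashed line marks equal change. Most genes lie along that line (r = 0.856 across genes). Sets simulated with no difference between groups, where noise is the only variance, gave 0.502 through the shared baseline arrays. Changes with no array in common still correlated by 0.759 and 0.806.

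The G2M genes lay between both levels after HDL. Their mean change from cholesterol to HDL was 0.31 and the median 0.20 (camera adjusted p = 2.51e-06; adjusted p = 0.454 with an estimated correlation; fry adjusted p = 0.14), and 67 of 91 members lay above 0. The mean change was 0.19 without HDL replicate 1 and 0.44 without HDL replicate 2. Only 3 members rose past the threshold over all genes and 0 fell, against 19 and 2 with p adjusted over the list alone. Of 56 members called lower after cholesterol in this normalization, 51 lay above 0 in the HDL comparison, 43 were still called below baseline, and the median share undone was 0.321. Both values use the cholesterol arrays on which these members were chosen. Sets simulated with HDL equal to cholesterol gave on average 30.0 of 56.9 members above 0 (at most 39). Their median share was 0.00815 (at most 0.0514). The observed means were taken as the true ones there, so choosing members on the cholesterol arrays may raise the share by more. Those sets drew the noise of each gene independently, with the same spread in all groups. Their ranges are therefore too narrow for genes that move together, and they cannot exclude a shift of the list on 1 array. Of the S list 7 members rose and 2 fell (12 and 7 over the list alone), with a mean change of 0.07 (camera adjusted p = 0.667). Of the G1 list 2 rose and 2 fell (18 and 6 over the list alone), with a mean change of 0.06 (camera adjusted p = 0.749).

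HDL-treated cells were last compared with baseline cells. The same 4 identifiers led this comparison as for cholesterol. ENSMUSG00000026822_at was higher by 9.28 ± 0.15 (SE; adjusted p = 4.06e-07) and ENSMUSG00000029371_at by 8.10 ± 0.10 (SE; adjusted p = 1.16e-07). ENSMUSG00000021390_at differed by -5.74 ± 0.12 (SE; adjusted p = 7.97e-07) and ENSMUSG00000069045_at by -4.96 ± 0.10 (SE; adjusted p = 7.97e-07). Of these, only ENSMUSG00000029371_at was also called between HDL and cholesterol, with a change of -0.87 ± 0.10 (SE; adjusted p = 0.00976). Limma called 3370 genes against baseline, with 1540 higher and 1830 lower, and 572 and 327 by at least 1 on the log2 scale. The cholesterol and HDL calls against baseline shared 2520 genes, and the covariance of their changes was 0.269 against 0.0116 simulated with no effect, a difference of 0.257. Of the G2M list 45 of 91 members were lower than at baseline and 2 higher (51 and 3 over the list alone), with a mean of -0.59 (camera adjusted p = 4.32e-10; adjusted p = 0.132 with an estimated correlation; fry adjusted p = 0.00908). Of the S list 28 of 95 were lower and 7 higher (31 and 8 over the list alone), with a mean of -0.20 (camera adjusted p = 0.00498; adjusted p = 0.0795 with an estimated correlation). Of the G1 list 20 of 125 were lower and 15 higher (26 and 17 over the list alone; camera adjusted p = 0.0851; adjusted p = 0.443 with an estimated correlation; fry adjusted p = 0.0412; with the preset correlation adjusted p = 0.0131 without baseline replicate 1). The count of 3370 was 1436 without baseline replicate 1 and 1263 without baseline replicate 2, and part of the overlap with the cholesterol calls may come from the shared baseline arrays.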

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

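Array quality weights, the shares undone from separate arrays and all alternatives for the cell cycle lists were chosen after the data had been seen. With a minimum change of 1 on the log2 scale, a stricter rule by construction, the counts were 962 genes for cholesterol against baseline, 170 for HDL against cholesterol, 899 for HDL against baseline, 52 called in the opposite direction after HDL and 613 still called against baseline. The one-way test per gene, with fewer degrees of freedom, called 38 for cholesterol against baseline and 0 for HDL against cholesterol. The cholesterol and HDL arrays alone gave 145 for the latter. Without each array in turn, where a lone array is assumed to vary like the other groups, cholesterol against baseline ranged from 2671 to 4238, HDL against cholesterol from 74 to 1656, HDL against baseline from 1263 to 4256, opposite calls from 20 to 667, genes still called from 973 to 2881, and the median share undone from 0.184 to 0.279. That share was 0.111 and 0.154 as a ratio of sums, and 0.143 and 0.171 as a median, from arrays not used to choose the 1052 and 937 genes; both the arrays and the genes differ there, and the 949 genes changed by at least 1 gave 0.170 on the shared arrays. With an estimated correlation the G2M list had an adjusted p of 0.102 for cholesterol against baseline, 0.454 for HDL against cholesterol and 0.132 for HDL against baseline, and with fry 0.14 for HDL against cholesterol; the other alternatives run for it stayed past the threshold in the same direction. For HDL against cholesterol, leaving out either baseline array gave the same fit as the cholesterol and HDL arrays alone. That change reflects the loss of the baseline pair from the estimate of the spread, not the values of the array left out. The same holds for HDL against baseline without either cholesterol array. Leaving out an array of a compared group likewise takes its pair out of the estimate of the spread, but it also changes the mean of that group. How far each accounts for the other changes with single arrays was not tested. Dim gene filter, variance trend, robust moderation, quantile normalization, median centring, array weights and the other deposited normalization kept the counts they were run for within 1.5 times. Array weights were not run for cholesterol against baseline, and the HDL arrays have one deposited normalization.

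With the replicate block the counts were 4640, 392 and 3285 for the comparisons in the order above, 197 opposite calls, 2440 still called and a share of 0.224, and the block changed no G2M call. The labels do not say that the numbers pair the arrays. The deviations of arrays with the same number correlated by 0.0160 between baseline and cholesterol, 0.133 between cholesterol and HDL and 0.00525 between baseline and HDL.

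For the named genes, 168 of 179 alternatives left them past the threshold in the same direction and 11 did not, 5 of those for ENSMUSG00000035042_at. The genes were chosen as the largest called changes, and some alternatives repeat a fit, so the 168 are not separate checks. The one-way test per gene was not run for HDL against baseline. In the other comparisons it kept only ENSMUSG00000029371_at, for cholesterol against baseline (adjusted p = 0.0314). The alternatives planned for the gene lists by symbol were not run, because the identifiers could not be matched to symbols. Dim genes near the array floor have compressed changes in RMA values, so the sizes of changes from or to the floor are less certain than their errors show.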

Other observations

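Of the 461 genes called between HDL and cholesterol, 131 were not called for cholesterol, and 92 of these rose and 39 fell. A missed call does not show that cholesterol left them unchanged: 61 of the 131 moved against the sign of their cholesterol change and 70 along it, and 28 were called for cholesterol in the first normalization, 13 of these against that change. A further 88 moved on in the direction of the cholesterol change, 76 of them upward and 12 downward, where independent lists would share 31.4 and 20.9. ENSMUSG00000028037_at is one of the upward group, at 6.49 ± 0.51 at baseline, 7.66 ± 0.30 after cholesterol and 11.25 ± 0.37 after HDL (SD, n = 2 each). The simulated sets in which HDL equalled cholesterol gave a mean of 0.02 such genes, which is low by construction because no gene truly differed between HDL and cholesterol there.

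The tests of the shared difference from baseline and of the G2M list below were chosen after the results were seen, and those of the spread of the HDL arrays before, apart from the check with an added shift.

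Cholesterol and HDL arrays shared much of their difference from baseline, with changes that correlated by 0.856 across genes. Noise of the shared baseline arrays was tested with changes that had no array in common, and these still correlated by 0.759 and 0.806, where that noise alone would give values under 0.1. Another candidate explanation is that the baseline cells came from another isolate, or from mice of another sex, than the loaded cells. ENSMUSG00000069045_at lay in the upper 50% of both baseline arrays and in the lowest 10% of all 4 loaded arrays, a difference of -4.98. A further 3 genes, with ENSMUSG00000029371_at among them, showed the reverse. That explanation also asks for the same level in cholesterol and HDL arrays. Those levels were 3.78 and 3.81 for ENSMUSG00000069045_at. For the 3 reverse genes they were 13.04 and 12.18 (ENSMUSG00000029371_at), 9.54 and 8.11, and 7.76 and 9.31. Loading could switch a gene in the same way and the labels give neither isolate nor sex. From these levels alone, preparation and treatment cannot be told apart for these genes or for any other difference from baseline. If all loaded cells were of the same origin, which the labels do not say, another origin of the baseline cells would by itself leave cholesterol and HDL cells alike. It would then not account for the change between them of the 461 genes called there. The opposite sign of 242 of these does not bear on it, because their cholesterol change is measured from baseline and shares the cholesterol arrays. ENSMUSG00000069045_at may be sex-linked, as may 4 further genes looked at after the results were seen, which the files cannot verify; 3 of the 4 were called lower (-0.63, -2.59 and -1.50 with cholesterol) and 1 higher (1.62) against baseline in cholesterol and HDL cells, 0 were called between HDL and cholesterol, and if these identities hold the values weigh toward a difference in sex.

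The G2M list fell with cholesterol and lay partly back toward baseline after HDL. A shift that depends on signal level is argued against for both steps: the median change of -0.64 lay below -0.09, the 2.5th percentile of 10000 random lists of matched signal, and the later change of 0.20 lay above 0.04, the matching upper percentile of such lists. Whether the later rise rests on one HDL array stays open, since the lower HDL array lay 0.15 above the higher cholesterol array but the HDL arrays differed by 0.26. No biological explanation was tested. Cell density, the cyclodextrin carrier, the 72 h or 144 h in culture and the origin of the baseline cells stay open as untested. With an estimated correlation the camera adjusted p values of 0.102 and 0.454 miss the threshold.

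The HDL arrays lay further apart than the others, with an SD of the difference of 0.27 against 0.17 and 0.18. A shift that depends on signal level is argued against in the deposited values, because after cyclic loess the SD was 0.270 against at most 0.183 in the other groups. As a check, a shift that grows with signal was added to 1 cholesterol array until that pair lay 0.274 apart. The same step removed that shift, back to 0.183. RMA had already brought the arrays to nearly the same distribution, so little of such a shift could remain and the outcome was largely set by the normalization. Whether the difference is noise that is random across genes stays open: HDL replicate 1 minus replicate 2 correlated by 0.107 with the cholesterol change, between the values of 0.1 and 0.3 set beforehand as limits. Of the 461 genes called between HDL and cholesterol, 321 changed more on HDL replicate 1, with a median ratio of replicate 2 to replicate 1 of 0.888. The share of the cholesterol change undone went the other way, at 0.195 on replicate 1 and 0.258 on replicate 2, and no biological explanation was tested.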
